A study of Mus musculus with 2 samples.

How the data were processed

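Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map GATA4, a zinc finger transcription factor that recognises GATA sequences, in mouse skeletal muscle myoblasts. Myoblasts are proliferating muscle precursors. Per the labels' protocols, these were derived from satellite cells, the stem cells of skeletal muscle, and were kept in growth medium with fetal serum and basic fibroblast growth factor. The donor stock carries a targeted Myf5 allele, as its name states. Chromatin was fixed with 1% formaldehyde and sheared to between 200 and 500 bp, per the labels' protocols. It was precipitated either with a mixture of 3 GATA4 antibodies or with control IgG. Library products of between 250 and 300 bp were sequenced as paired reads of 150 bp on a HiSeq 2500. There was 1 library per antibody and no replicate.

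Per the submitters' processing notes, CASAVA 1.8 and Bowtie were used and the genome build was GRCm38 (mm10). Per the file header, peaks were called with MACS run in Galaxy. The MACS and Bowtie versions, the read filters, the duplicate handling, the calling threshold and the use of the IgG library as control are not given in the sources used here. The authors deposited 1 peak list with a start, an end and a MACS score per peak. That score is the authors' own value in each peak and was compared here only between peaks of this list. It was used to describe, rank and filter peaks, to compare peaks near and far from genes, and to read off the read numbers behind the most frequent scores. Peak starts were converted from 0-based to 1-based. Read counts and coverage of either library were not analysed here, so the depth is unknown and no background measured in the IgG library can be set beside the peaks. With 1 library per antibody nothing was tested between libraries. Each p-value below describes where the peaks of this single list lie, and peaks and genes are not biological replicates.

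Genes were taken from a RefSeq gene table of GRCm38.p6, the same build, with 49943 genes on the chromosomes that held peaks. Of these, 21887 were protein coding and 12727 were lncRNA genes. All 397 symbols of the 19 gene lists matched the table. The table gives the start and end of each gene but no strand, exon or untranslated region. The plan made before the data were examined used transcription start sites. Windows around either end of a gene took their place, so a peak near a gene end can lie at the start or at the end of transcription. Genome sequence was not used here. The planned tests of GATA and other motifs, of GC content, of repeats, and of exons and untranslated regions were therefore not run, and whether the peaks hold GATA motifs is left open.

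A peak was assigned by its centre. For genomic features, peak centres were classed as within 1 kb of an end of a protein coding or lncRNA gene, inside such a gene, or outside. They were compared with 1000 placements of the peaks at random positions of the same chromosome, from 3 Mb to the last annotated gene end. A two-sided permutation p was used, with Benjamini-Hochberg adjustment over the classes. Assembly gaps within that range were not excluded, although the plan excluded them. Scores of peaks within 1 kb and over 10 kb from a gene end were compared by a two-sided permutation test of the medians with 100000 resamples. For gene lists, protein coding genes with a peak centre within 10 kb of either end were counted. Each list was compared with all other protein coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 19 lists and a threshold of 0.05. Exact (Clopper-Pearson) 95% intervals were given for shares and exact Poisson intervals for peaks per Mb, both for counting error only. Chromosome X was compared with the autosomes by a two-sided exact binomial test on annotated length.

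The lists and the rule for the genes named were fixed before the data were examined. The rule names the 20 peaks with the highest score and a set of 17 myogenic, cardiac, cell cycle and brown fat genes. It also names up to 4 members per list by the highest score of a peak within 10 kb, and the 10 genes with the most such peaks, with ties kept. The lists cover myogenic regulators, contractile, cardiac, smooth muscle, cell cycle, signalling, brown fat, matrix and satellite cell genes. Further lists hold markers of other cell types, genes that GATA4 is known for in liver, gut and gonad, and housekeeping genes.

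Alternatives fixed before the data were examined were windows of 500 bp for features and of 1 kb and 50 kb for gene lists, nearest gene assignment, peak width in place of the score, and the 8769 peaks above the median score. Chosen after seeing the data were gene groups drawn up from single genes, families of gene symbols, the gene span with 10 kb, random lists matched on gene length and chromosome class, rotated peaks, only protein coding genes, only genes with an NM transcript, only peaks within 1 kb or over 10 kb from gene ends for the chromosomes, a minimum of 7 reads in the drawing of reads, bins of matched gene number, and the removal of chromosome 10. The list test was tested on simulated data with the real genes and as many peaks, for 200 changed and 200 unchanged lists of 20 genes. Peaks were placed at random positions, without the clustering of the real ones, and unchanged lists were random genes. Peaks were then given to 50% of a changed list's genes, on top of those from the random placement. The test recovered 97.5% of changed lists and called 2% of unchanged lists. Changed and unchanged lists were equal in number, and the adjustment is less strict when many of the lists tested together are changed. Few lists of the report passed, so the 97.5% can overstate how often a changed list would be recovered there. A list that did not pass is therefore not shown to be unchanged. Smaller changes were not simulated, and the 2% does not cover false calls from gene length or from peaks at active genes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.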

Results

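The deposited peak list held 17539 GATA4 peaks from 1 GATA4 ChIP library of cultured mouse myoblasts, with 1 IgG ChIP library sequenced beside it. The peaks did not overlap each other and covered 13.5 Mb. Their median width was 745 bp, with quartiles of 589 and 899 bp and a range from 212 to 2990 bp. The MACS score, the authors' value per peak, had a median of 99.3 and ran from 50.1 to 861. There were no replicates, so no error between libraries can be given. The comparisons below ask where in the genome, and near which genes, GATA4 peaks were found in proliferating muscle precursors.

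GATA4 peaks were concentrated at the ends of genes, although most lay farther away. Within 1 kb of an end of a protein coding or lncRNA gene there were 2409 peaks, or 13.7% of all peaks. Random placements put 4.91% there on average, with 95% of placements between 4.58% and 5.20%, so the share was 2.80 times that of chance. A further 9000 peaks, or 51.3%, lay inside genes, 1.14 times the placed share of 44.9%. Placements could fall in assembly gaps, where no peak can lie, so this small excess may be inflated. The 6130 peaks outside genes made up 35.0%, against 50.2% of placed peaks. For each of these classes the adjusted permutation p was 0.0020, the smallest that 1000 placements can give. Over 10 kb from any gene end lay 9751 peaks, or 55.6%.

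Peaks near gene ends scored lower than distal ones. The 2409 peaks within 1 kb of an end had a median score of 86.7, with quartiles of 71.6 and 119. The 9751 peaks over 10 kb away had a median of 105, with quartiles of 80.5 and 144. The medians differed by -17.91 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). Peak width went the other way, with a median of 764 bp near gene ends and 742 bp far from them (permutation p = 0.00011).

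The highest-scoring peak lay at chromosome 10, 6838655 to 6840463, inside Oprm1, the gene of the mu opioid receptor, with a score of 861. The next, with a score of 736, lay at chromosome 4, 59314824 to 59316944, inside Susd1. A peak at chromosome 19, 36118687 to 36121442, was 2756 bp wide and scored 637. It overlapped the higher-coordinate end of Ankrd1, which encodes a titin-associated ankyrin repeat protein of striated muscle. Peaks inside St3gal1 (score 620), Syne1 (597) and Cdh2 (585) were also among the 20 highest. Syne1 encodes the nuclear envelope protein nesprin-1, and Cdh2 encodes N-cadherin. The others inside genes lay in Klhl1 (score 657), Syn3 (561) and Mbp (558). Esm1, 4930467E23Rik, Zeb1, Gm13289, Pthlh and Tnp1 were the nearest genes of peaks with scores of 676, 660, 603, 595, 580 and 561, at 17.3, 31.0, 31.1, 0.087, 15.3 and 23.2 kb from the gene. The nearest genes of the remaining peaks, Atp2b1, Kcnc2, Mettl11b, Marcks and Eya4, were 121 to 363 kb away. In all, the centres of 8 of these 20 peaks were inside a protein coding gene, and 7 of the 20 were on chromosome 10. The peaks of Klhl1, Pthlh and Syn3 were only 253, 345 and 452 bp wide, below the lower quartile of 589 bp. The others were 1042 to 2756 bp wide. Duplicate handling is not given, so a high score in a narrow peak is uncertain. Gm13289 lies close to Ifnz on chromosome 4, in a gene cluster where the division of reads among copies is not given either.

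Of the 17 genes named in advance, 6 had a peak within 10 kb of an end. Myod1, which encodes the myogenic determination factor MyoD, had the most peaks nearby. It lies at chromosome 7, 46376474 to 46379092, and had 6 peaks within 50 kb. A peak with a score of 227 (46378823 to 46380381) overlapped the higher-coordinate end of the gene. A pair at 22.5 and 25.7 kb on the lower-coordinate side scored 185 and 250. Myf5, a related determination factor, lies at chromosome 10, 107482908 to 107486927. Its 3 peaks within 50 kb scored 94.0 at 8.41 kb on the lower-coordinate side, and 138 at 12.95 kb and 229 at 19.9 kb on the higher-coordinate side. Distance alone does not assign them to Myf5, and Myf6, also on chromosome 10, had a peak within 10 kb of its own ends. Pax7, the satellite cell transcription factor, had a peak inside the gene with a score of 97.0 and another 7.75 kb outside it with a score of 91.2. Myh3, the embryonic myosin heavy chain, had a peak centred 0.808 kb from the gene with a score of 115. Gata6 had a peak inside the gene, 0.332 kb from an end, with a score of 68.7. Nppa, encoding atrial natriuretic peptide, had a peak at 2.85 kb with a score of 110. Among peaks above the median score only Myod1, Myh3 and Nppa kept a peak within 10 kb, and within 1 kb only Myod1, Myh3 and Gata6 had one.

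**Figure D1:**
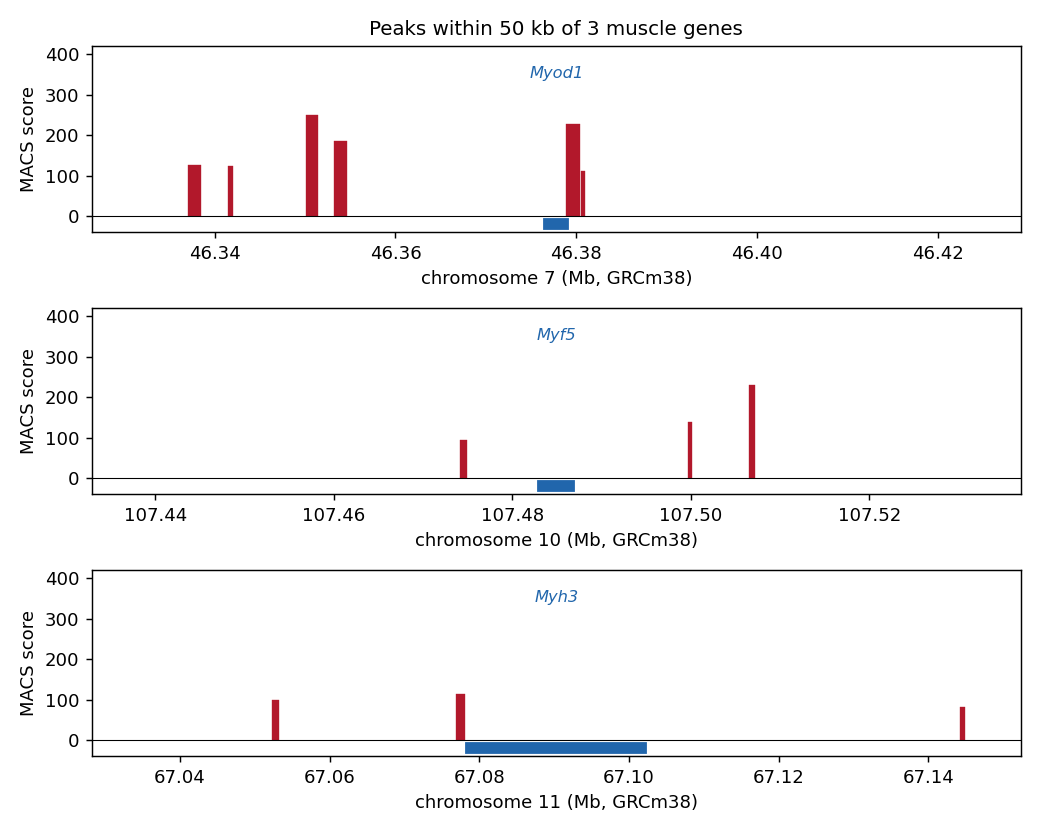
MACS score (vertical axis) of each peak against its position in Mb on GRCm38 (horizontal axis) within 50 kb of Myod1, Myf5 and Myh3; red bars span the peaks and blue boxes the genes. Myod1 has 6 peaks in view, Myf5 has 3 and Myh3 has 3.

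The other named genes had none within 10 kb of an end. Mef2c had a peak in the middle of the gene with a score of 91.3. Myh6, the alpha cardiac myosin heavy chain, Nkx2-5, Ucp1 and Cdk4 had their nearest peaks at 29.5, 23.9, 17.2 and 21.4 kb. For 6 genes the nearest peak was over 50 kb away. These were Myog at 54.1 kb, Cdkn1a at 56.6 kb, Ccnd2 at 67.6 kb, Acta1 at 105 kb, Gata4 itself at 106 kb and Prdm16 at 462 kb. Gata4 and Myh6 lie on chromosome 14, which had the lowest peak density of the autosomes.

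Across all protein coding genes, 5741 of 21887, or 26.2%, had a peak within 10 kb of an end. Genes of the extracellular matrix and myogenic regulators had peaks more often. Of 25 matrix and fibroblast genes, 16 had a peak, or 64.0% (95% interval 42.5% to 82.0%; Fisher's exact test, adjusted p = 0.0015). They included the laminin subunit genes Lama2, with a peak of score 280 at an end of the gene, Lamb1 (224) and Lamc1 (201), and the collagen gene Col3a1 (174). Col1a1, Col1a2, Col4a1, Col4a2, Fn1, Sparc, Postn and Vim were also among the 16, while Dcn, Lum, Thy1 and Tcf21 had none. Of 26 myogenic regulators, 14 had a peak, or 53.8% (33.4% to 73.4%; Fisher's exact test, adjusted p = 0.027). Besides Myod1, the highest-scoring were near Mef2a, a MADS box factor (score 243 at 8.97 kb), Msgn1 (213 at 1.71 kb) and Tcf3, which encodes E proteins that pair with MyoD (213 at 0.047 kb). Myf5, Myf6, Pax7, Mymx, Mef2d, Six4 and Tcf12 were among the 14, and Myog, Pax3 and Mymk were not. Neither list passed within 1 kb (exact test, adjusted p = 0.14 each), within 50 kb (0.14 and 0.059) or against random lists matched on gene length and chromosome class (permutation, 0.052 each). Without chromosome 10, which holds Myf5, Myf6 and Tcf3, the myogenic list had 47.8% against 25.5% of others (Fisher's exact test, adjusted p = 0.13). Among higher-scoring peaks it had 30.8% against 12.8% and also missed the threshold (Fisher's exact test, adjusted p = 0.0501).

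**Figure D2:**
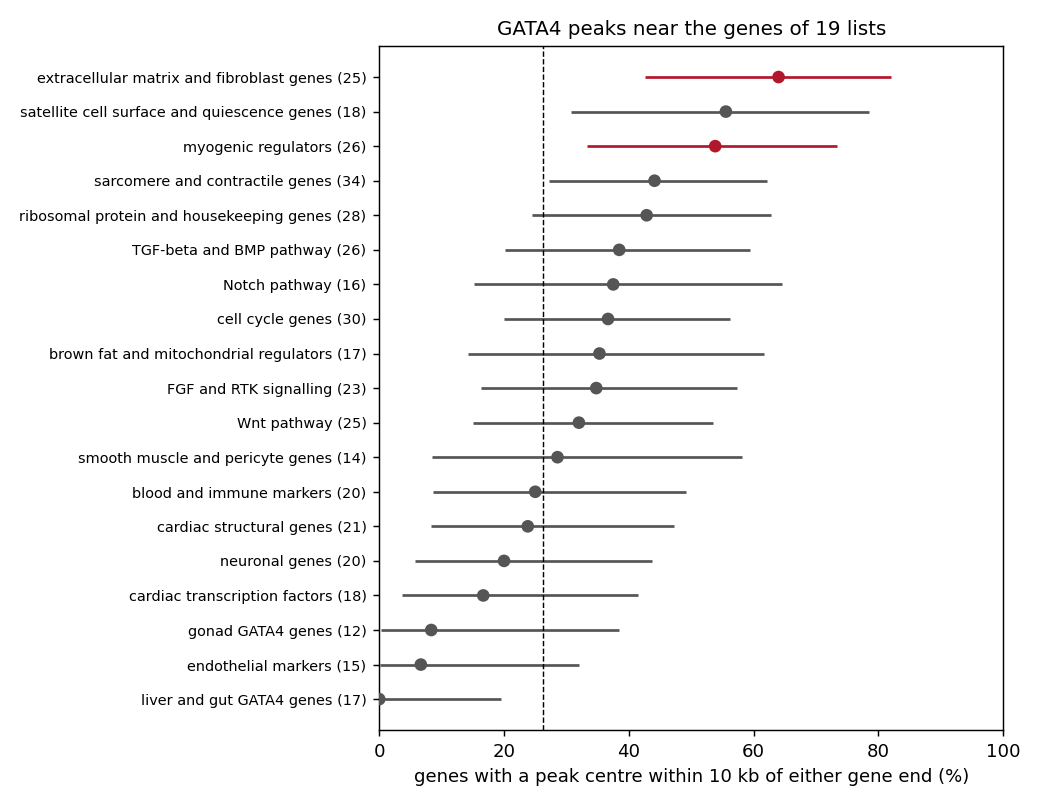
Share of each list's genes with a peak centre within 10 kb of either gene end (horizontal axis, %), with exact 95% intervals and the number of genes in brackets; the dashed line is the share of other protein coding genes and red marks lists past the adjusted threshold of 0.05. Matrix genes (64.0%) and myogenic regulators (53.8%) are red, and liver and gut genes are at 0%.

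Other muscle lists had high shares that did not pass the adjusted threshold. Of 18 satellite cell surface and quiescence genes, 10 had a peak, or 55.6% (Fisher's exact test, adjusted p = 0.057). They included Itga7, the laminin-binding integrin of muscle, with a score of 185 at 1.95 kb, Ncam1 (182), Sdc4 (177) and Heyl (151). Calcr, Cdh15, Chrdl2, Cxcr4, Foxo1, Megf10, Spry1 and Tek had none within 10 kb. This list passed the threshold among the peaks above the median score, where 44.4% of its genes had a peak against 12.8% of others (Fisher's exact test, adjusted p = 0.018). It also passed with the nearest gene (72.2% against 32.7%, exact test, adjusted p = 0.0044) and with the gene span and 10 kb (0.0096). It did not pass within 1 kb (0.14) or 50 kb (0.198), against matched lists (permutation, 0.211) or without chromosome 10 (0.151). Of 34 sarcomere and contractile genes, 15 had a peak, or 44.1% (exact test, adjusted p = 0.11), with Tpm2 (score 271), Myl1 (167), Tpm1 (153) and Actn3 (138) highest. The Tpm2 peak was also within 10 kb of Tln1, so it cannot be assigned to either gene. Ckm, Acta1, Des and the adult fast myosin genes Myh1, Myh2 and Myh4 had no peak within 10 kb.

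Lists of cardiac genes did not stand apart from other genes. Of 18 cardiac transcription factors, 3 had a peak, or 16.7% (exact test, adjusted p = 0.59). These were Zfpm2, encoding the GATA cofactor FOG2 (score 158 at 2.19 kb), Gata6 and Srf. Of 21 cardiac structural genes, 5 had a peak, or 23.8% (exact test, adjusted p = 1). The 4 highest were near Nppa (110), Actc1 (107), Tnnt2 (106) and Myh7 (87.7). Smooth muscle and pericyte genes had peaks at 4 of 14, or 28.6% (exact test, adjusted p = 0.86), with Pdgfrb highest at 233.

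Genes that GATA4 is known to regulate in other organs had few peaks within 10 kb. None of 17 liver and gut genes, such as Alb, Hnf4a and Fabp1, had a peak within 10 kb (0%, 95% interval 0% to 19.5%; Fisher's exact test, adjusted p = 0.057). The list passed only when peaks inside the gene were counted too, a choice made after seeing the data, with 0% against 33.3% of other genes (Fisher's exact test, adjusted p = 0.0096). Within 50 kb, 47.1% of its genes had a peak against 56.0% of others (Fisher's exact test, adjusted p = 0.56), and against matched lists the adjusted permutation p was 0.052. Of 12 gonad genes only Amh had a peak, with a score of 119 at 6.65 kb (8.33%; exact test, adjusted p = 0.40). Endothelial markers had a peak at 1 of 15 genes, Sox18 (6.67%; exact test, adjusted p = 0.37). Blood and immune markers had peaks at 5 of 20 (25%; exact test, adjusted p = 1), among them Cd79a (182) and Csf1r (105). Neuronal genes had peaks at 4 of 20 (20.0%; exact test, adjusted p = 0.74), with Map2 at 350 and Tubb3 at 251 highest.

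Signalling and cell cycle lists had shares between 32.0% and 38.5% within 10 kb, none past the threshold. Of 26 TGF-beta and BMP genes, 10 had a peak (38.5%; exact test, adjusted p = 0.40), led by Smad3 (score 300 at 3.72 kb), Smad1 (182), Id3 (176) and Fst (167), which encodes the myostatin antagonist follistatin. Of 16 Notch genes, 6 had a peak (37.5%; exact test, adjusted p = 0.59), led by Notch1 (159). Of 30 cell cycle genes, 11 had a peak (36.7%; exact test, adjusted p = 0.40), led by Ccnb1 (188), and with Cdk6 (122), Cdkn2b (108) and Myc (106). Of 17 brown fat and mitochondrial regulators, 6 had a peak (35.3%; exact test, adjusted p = 0.59), among them Pparg (154) and Ppargc1a (117). Of 23 FGF and receptor kinase genes, 8 had a peak (34.8%; exact test, adjusted p = 0.59), among them Frs2 (216), Vegfa (175) and Dusp6 (170). Of 25 Wnt genes, 8 had a peak (32.0%; exact test, adjusted p = 0.63), led by Apc (151). With each peak given to its nearest gene, TGF-beta and BMP genes (65.4% against 32.7% of others, exact test, adjusted p = 0.0052) and Notch genes (62.5%, exact test, adjusted p = 0.049) passed. That test was not matched on the spacing of genes. Under the same choice cardiac transcription factors and cardiac structural, endothelial and neuronal genes also moved above other genes, without passing. Housekeeping genes moved slightly below them. The nearest-gene shares can therefore reflect the choice of assignment. Within 50 kb of an end, 93.8% of Notch genes had a peak against 55.9% of others (Fisher's exact test, adjusted p = 0.032), and 92.9% of smooth muscle genes did (Fisher's exact test, adjusted p = 0.0499).

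Housekeeping genes also had peaks close to their ends. Of 28 ribosomal protein and housekeeping genes, 12 had a peak within 10 kb, or 42.9% (Fisher's exact test, adjusted p = 0.17). Within 1 kb the share was 32.1% against 9.44% of other genes (Fisher's exact test, adjusted p = 0.015). Among them were Eef2 (score 167 at 0.289 kb), Eef1a1 (149 at 0.018 kb) and Polr2a (146 at 0.055 kb).

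The genes with the most peaks within 10 kb fell into a few places. Gm40365, Gm36327, Gm40363, Gm40367 and Gm40364, neighbours on chromosome 6 between 47662592 and 47738326, had 13, 12, 12, 11 and 9 peaks. These windows share peaks. Gm13276, Gm13277 and Ifnz, neighbours on chromosome 4, had 8 each. How reads were divided among copies in such gene clusters is not given in the sources used here, so these counts are uncertain. Cirbp, encoding a cold-inducible RNA-binding protein, and its neighbour Midn on chromosome 10 had 9 each. The windows of Cirbp and Midn overlap, as do those of the chromosome 4 genes, so their counts can include the same peaks. Btg2, an antiproliferative gene, had 8. Mapk6, encoding the kinase ERK3, also had 8 within 10 kb of its ends, and 8 peaks lay inside the gene.

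Peaks were spread unevenly over the chromosomes. Chromosome X held 202 peaks, or 1.205 per Mb (95% Poisson interval 1.04 to 1.38), against 7.21 per Mb over the 19 autosomes. The ratio was 0.167 (exact binomial test, two-sided, p = 2.86e-270). Chromosome Y held 5 peaks. Among autosomes, chromosome 10 had the highest density, with 1635 peaks or 12.8 per Mb (12.2 to 13.5), 1.86 times that of the other 18 autosomes (exact binomial test, p = 9.64e-107). The next highest was chromosome 13 at 8.52 per Mb. Chromosome 14 had the lowest, with 411 peaks or 3.38 per Mb (3.06 to 3.72). The median score was 110 on chromosome 10 and 92.9 on chromosome X, while on chromosome 14 it was 97.0, the same as on chromosomes 2, 11, 12, 16 and 17. Chromosomes 10 and 14 were singled out after their values were seen, and the binomial tests cover counting error only.

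**Figure D3:**
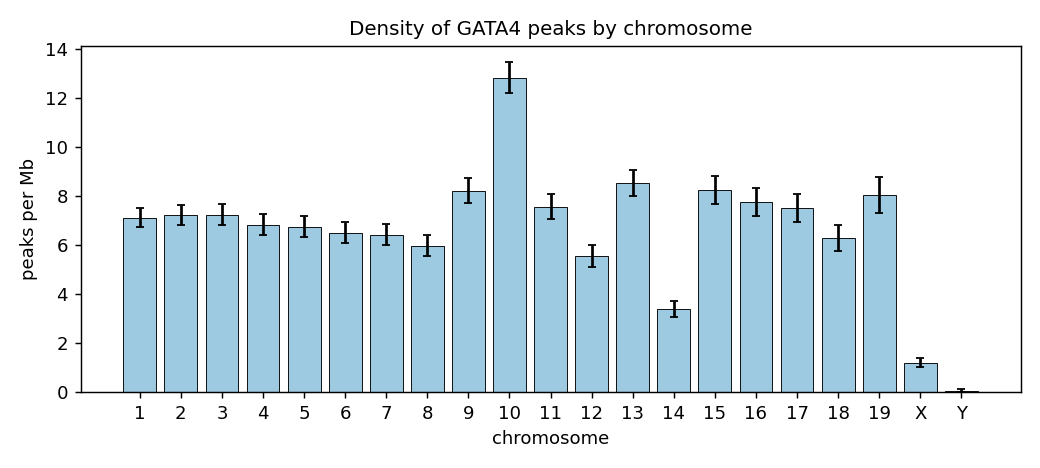
GATA4 peaks per Mb of annotated length (vertical axis) on each chromosome (horizontal axis), with exact 95% Poisson intervals for counting error. Chromosome 10 stands at 12.8 per Mb and chromosome X at 1.205 per Mb.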

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

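Fits added after seeing the data were the gene span, the matched lists, the rotation, the NM and protein coding gene sets, the chromosome ratios within 1 kb and over 10 kb from gene ends, the matched gene number and the runs without chromosome 10. The number of gene lists past the threshold, 2 in the report, was 1 within 1 kb of a gene end, 6 with the nearest gene, 4 with the gene span and 10 kb, 1 without chromosome 10 and 0 against matched lists, where both had an adjusted permutation p of 0.052 and an unadjusted p of 0.0040 (matrix genes) and 0.0078 (myogenic regulators). The cause was not tested. Lists that passed only under another choice were the satellite cell (adjusted exact p = 0.0044), TGF-beta and BMP (0.0052), sarcomere (0.021) and Notch genes (0.049) with the nearest gene, the satellite cell (0.0096) and liver and gut genes (0.0096, lower) with the gene span, satellite cell genes (0.018) among higher-scoring peaks, Notch (0.032) and smooth muscle genes (0.0499) within 50 kb, and housekeeping genes (0.015) within 1 kb. The matrix list also missed the threshold within 1 kb and 50 kb (Fisher's exact test, adjusted p = 0.14 in each), and the myogenic list within 1 kb (0.14), within 50 kb (0.059), among higher-scoring peaks (0.0501) and without chromosome 10 (0.13). Some lists that had not passed changed the sign of their difference from other genes, given here in percentage points. Within 1 kb these were smooth muscle (-9.47), cardiac structural (0.057) and neuronal genes (5.54). Within 50 kb they were cardiac structural (10.7), endothelial (17.4), blood (9.04) and gonad genes (2.37). With the nearest gene they were cardiac transcription factors (17.3), cardiac structural (14.9), endothelial (13.95), neuronal (17.3) and housekeeping genes (-0.58). Among higher-scoring peaks they were cardiac structural (1.49), Wnt (-4.80), brown fat (-1.03) and blood genes (2.20). With the gene span they were cardiac transcription factors (0.026), cardiac structural (4.79) and neuronal genes (1.69). They were smooth muscle genes (-0.775) with matched lists, and cardiac structural (0.75) and FGF genes (-0.57) without chromosome 10. None of these passed the threshold, and the cause was not tested. The comparison of peaks near and far from genes reversed when width replaced the score, at 22 bp wider near genes, and the cause was not tested. The enrichment near gene ends ran from 2.06-fold among higher-scoring peaks to 3.99-fold within 500 bp. The ratio of chromosome X ran from 0.108 within 1 kb of gene ends to 0.200 over 10 kb from them, and that of chromosome 10 from 1.62 within 1 kb of gene ends to 2.12 among higher-scoring peaks. Alternatives on motifs, GC content, soft-masked repeats and a window set by strand were not run, since genome sequence and strand were not used here. No paired analysis was possible because there was 1 library per antibody and 1 peak list. Depth limits the list to peaks above the caller's threshold, so a gene without a peak is not shown to lack GATA4.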

Other observations

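All tests in this part were chosen after the peak list was seen, and those of the Myf5 segment, of extra copies and of housekeeping genes after the values they measure. Gene groups that the report does not describe also had peaks nearby. Each group below was drawn up because of one gene with many or strong peaks, which was then left out. Of 24 YAP and TEAD target genes, 13 had a peak within 10 kb of an end, or 54.2%, against 26.2% of other genes (Fisher's exact test, two-sided, p = 0.0040). They included Ccn2, with a score of 297, Gadd45a (169), Axl (147) and Ccn1 (144), and the group was drawn up from the strong peak at Ankrd1. Of 21 immediate early genes, drawn up from Btg2, 13 had a peak, or 61.9% (Fisher's exact test, p = 0.00061), among them Atf3 (217), Egr2 (170), Dusp1 (167), Zfp36 (154) and Junb (138). Of 26 actin cytoskeleton and focal adhesion genes, drawn up from the gene Palld, 15 had a peak, or 57.7% (Fisher's exact test, p = 0.0010), among them Pxn (227), Itga5 (174), Actn4 (156) and Cnn3 (152). The 15 also include Tln1, whose strongest peak (271) is shared with Tpm2. Adjusted over these groups, the p-values were 0.0040, 0.0016 and 0.0016. Against lists matched on gene length and chromosome class, the adjusted permutation p-values were 0.017, 0.0024 and 0.0060, adjusted over these groups only, and without chromosome 10 all stayed past the threshold. The FGF and receptor kinase genes of the report did not pass (34.8%), and what these groups share was not tested.

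Sensory receptor and keratin genes had few peaks. Of 1480 olfactory and vomeronasal receptor genes 38 had a peak within 10 kb, or 2.57% (Fisher's exact test, adjusted p = 1.77e-143). Of 53 keratin genes 1 did (1.89%, Fisher's exact test, adjusted p = 5.27e-06). These p-values treat each gene as independent, although neighbouring genes can share a peak or an empty stretch, and so can overstate the evidence. Neither family was compared with lists matched on gene length, and how reads were divided among similar copies is not given. Zinc finger genes named Zfp had 26.7%, the level of other genes (Fisher's exact test, adjusted p = 0.82), and 18 of 44 collagen genes had a peak (40.9%, adjusted p = 0.0504). Peaks also clustered along the genome. Another peak lay within 10 kb of 37.2% of peaks, against 13.9% of randomly placed ones (95% of placements between 13.2% and 14.7%). The genes with the most peaks inside them were long: Pakap with 25 in 463 kb, Dlg2 with 23 in 1973 kb, Pde4d with 19 in 1302 kb, Zbtb20 with 19 in 759 kb, and Dlgap1, Lama2 and Nfia with 18 each in 852, 636 and 541 kb. Palld, named above, had 15 in 391 kb. Among the genes named here, density ran from 1.17 peaks per 100 kb in Dlg2 to 5.41 in Pakap. The 19 autosomes had 7.21 per Mb, so length alone does not give these counts. The genes were picked for their counts, which favours a high density.

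On chromosome 10 all 13 windows of 10 Mb were denser than the median window of the other autosomes (7.05 peaks per Mb, passed by 116 of 232 windows), with 7.3 to 18.2 per Mb, although the lowest, from 100 to 110 Mb, showed no clear excess. Over the chromosome the excess was 1.62-fold within 1 kb of gene ends and 1.97-fold over 10 kb from them. Gene density does not account for this excess, since the ratio was 1.85 (95% bootstrap interval over 10 Mb blocks 1.60 to 2.09) against bins with as many genes. A segment of another strain confined to 20 Mb around the targeted Myf5 locus does not either, with a ratio of 1.89 (1.65 to 2.18) outside it. A longer segment was not tested. Extra copies of chromosome 10 in the cultured cells may be the source and predict these 13 windows, but denser regulation of this chromosome in myoblasts would give them too, and read coverage of the IgG library, which would decide, was not analysed here.

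The low number of peaks on chromosome X was not explained by gene density, with a ratio of 0.171 (0.125 to 0.216) at matched gene number. A single X per cell may lower it, since fewer reads would be drawn from it. When 50% of the reads of autosomal peaks at the background score steps were drawn, 0.227 of them kept 8 reads and 0.356 kept 7, the lowest number on a step, both above the observed ratio of 0.167 (0.145 to 0.192). The share depends on this assumed minimum and so decides nothing, and with the sex of the animals not given in the sources used here, a single copy remains open beside other causes. On chromosome 14 the windows from 0 to 50 Mb had 4.50 to 8.80 peaks per Mb and those from 50 to 120 Mb had 0.20 to 3.40, with a ratio for the whole chromosome of 0.503 (0.337 to 0.672) at matched gene number.

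Peaks within 1 kb of the ends of housekeeping genes raise the question whether part of the list reflects unspecific enrichment at active genes. The genes of the 2 lists that passed the threshold had a peak within 10 kb in 30 of 51 cases (58.8%), and housekeeping genes in 12 of 28 (42.9%), with p = 0.239 by Fisher's exact test. That comparison decides nothing, since the lists were picked for passing at the same window and the counts are small. Within 1 kb the shares were 23.5% and 32.1% (Fisher's exact test, p = 0.435). Unspecific enrichment and binding of GATA4 at active promoters both stay open, also for the gene groups above.

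The scores themselves carry a trace of the read numbers. The 11 most frequent scores, from 71.6 to 213, were matched within 0.022 by -10 log10 of a Poisson upper tail with a mean of 0.5075 reads, for 8 to 18 reads or more. By this reading 4703 peaks, or 26.8%, lay within 0.03 of a step, with 7 to 32 reads and a median of 11 reads (10 if the caller counts reads above the number). The share on a step was 21.9% on chromosome 10, 27.2% on the other autosomes and 35.6% on chromosome X.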
